A study of Mus musculus with 11 samples.

How the data were processed

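RNA sequencing was analysed from 11 libraries of thioglycollate-elicited peritoneal macrophages from female mice, 5 given a negative control and 6 given a microRNA-150 (miR-150) mimic. Per the series' design text, an additional control sample was prepared and left out by the submitters because its RNA was improperly fragmented, and it was not analysed here. Group and replicate number were taken from the sample titles. The labels do not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

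The deposited table holds 32265 rows for 31936 Ensembl genes. Per the submitters' processing notes, STAR, Subread, featureCounts and edgeR were used. Versions, genome build, annotation and strand setting were not given in the sources used here. The expression values deposited by the authors are log2 CPM (CPM, reads scaled to a common library total). From the values themselves, each is the log2 of a whole number of reads plus 0.5, divided by a scaled library total. Whole reads were recovered from those steps for 100% of values, within 0.01 read. The authors' scaled totals lay between 0.97 and 1.03 times the recovered totals, which ranged from 18538509 to 25473814 reads per library. The authors' deposited table also gives a log2 fold change per gene with confidence limits, and a p-value and adjusted p-value per gene; the test behind these deposited p-values was not given in the sources used here. Genes that share sequence with near-identical copies, such as the histone H4 genes and the small structural RNAs, are uncertain, because how the authors' counting split or dropped shared reads is not known.

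Because the table proved to hold log2 values and not raw counts, the test fixed for that case was used. Linear models with a group term only were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) to the deposited log2 CPM, with empirical Bayes moderation using an intensity trend and robust settings. Genes with log2 CPM of at least -1 in at least 5 libraries were kept, which left 12969. That filter was chosen once the unit was known, early in the work, and not changed afterwards. Every adjusted p-value of a gene is limma's with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. On simulated data for these 12969 genes, 98% of genes given a log2 change of -1 or 1 were recovered, as were 72% of those at -0.5 and 82% of those at 0.5, and 6.42% of the calls were false. The simulated genes varied independently, with the same dispersion for every gene and both groups and no trend with transcript length. These rates may therefore not hold for the real libraries.

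The 36 gene lists (731 distinct genes), the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 called genes with the largest rise and the 10 with the largest fall, with a mean log2 CPM of at least 1 and an established symbol. It also named Scd2, Myb, Cxcr4, Abca1 and Vegfa whatever their values, up to 4 members of each list past the threshold, and up to 2 members of each other list, by smallest p. Lists with at least 3 tested members were tested with camera, using a preset correlation between genes of 0.01 and adjustment over the lists, and again with an estimated correlation and with fry.

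Sites for miR-150-5p (positions 2 to 8 of the microRNA) were searched in the longest annotated 3′ UTR of each protein-coding gene, from the GENCODE M21 annotation of GRCm38, joined to the table by Ensembl gene ID. All coordinates are from that annotation, which may not be the one the authors used. Genes with a site were compared with the other genes by camera, with 1000 random gene sets matched on 3′ UTR length and expression, and with the genes matching each of 200 random 7-mers of the same GC count. Transcript length is that of the longest annotated transcript. Tables and figures used pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Replicate libraries differed beyond sampling noise in every pair (chi-square per degree of freedom from 2.57 to 44.1), so none was treated as a duplicate.

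Alternatives covered the scaling, the filter, the pseudocount, a voom fit with sample weights on the recovered reads, the threshold, the replicate number as a block, each library left out in turn, the set test and the site definition. A filter on mean expression, a per-library correction for transcript length (lowess, span 0.3) and the omission of mimic replicates 3, 4 and 6 were added after the data were seen. So were camera runs with an estimated correlation under the length correction, the voom fit and each omission. Negative binomial count models were planned for a table of counts and were not run on the recovered reads, which entered the voom fit and the alternative scalings and pseudocounts.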

Results

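Gene expression was measured by RNA sequencing in mouse peritoneal macrophages, the inflammatory macrophages that enter the abdominal cavity after an injection of thioglycollate. The cells had received either a miR-150 mimic, a synthetic RNA that raises the activity of this microRNA, or a negative control. The series concerns macrophage miR-150 in the abnormal vessel growth of age-related macular degeneration. The 5 control libraries held 18538509 to 22668862 reads assigned to genes and the 6 mimic libraries 20313901 to 25473814. Mature microRNAs are not measured by such libraries, so the level of miR-150 itself was not checked. Reads from its host locus, Mir150, numbered 4 over the control libraries and 15 over the mimic libraries.

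The comparison asks which transcripts change when macrophages receive the mimic. Of the 10 largest rises, 3 were in members of the interferon-response list (Ifi44, Ifit2 and Ifit3), and 16 members of that list stood among the 50 largest. These counts cover only the 41 genes listed beforehand, which leave out the related genes Ifit3b and Ifit1bl1. Ifit3, an antiviral effector (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, GRCm38), averaged a log2 CPM of 4.29 ± 0.35 (SD, n = 5) in controls and 7.90 ± 0.072 (SD, n = 6) with the mimic. It was therefore 12.2-fold higher, a log2 fold change of 3.61 ± 0.12 (SE; limma adjusted p = 1.53e-10). The other members of the 10 largest rises were Ms4a4c (log2 fold change 4.28), Ifi44 (3.83), Ifit2 (3.77), Ifit3b (3.74), Slfn1 (3.53), Pydc3 (3.42), Pydc4 (3.21), Ifit1bl1 (3.17) and Slfn4 (3.04). For each of these 10 genes all 6 mimic libraries lay above all 5 controls. Ifit2, Ifit3, Ifit3b, Ifit1bl1, Pydc3, Pydc4, Slfn1 and Slfn4 belong to families of similar neighbouring genes, so their single values are uncertain. Shared sequence was not measured for any of the 10. Of 12969 genes tested, 1997 were higher and 1895 lower with the mimic, 30% in all. Most shifts were small: the median absolute log2 fold change of the called genes was 0.26, and only 149 rose and 44 fell by at least a log2 unit. The authors' deposited table calls 1498 genes higher and 1441 lower, and 2766 genes were called in the same direction by both.

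All 39 measured members of the interferon-response list rose, with a median log2 fold change of 1.68, or 3.21-fold (camera adjusted p = 1.35e-61; adjusted p = 0.027 with an estimated correlation). Adjusted over the list alone, all 39 were again higher. With an estimated correlation the list missed the threshold without mimic replicate 1 (adjusted p = 0.0732), without mimic replicate 2 (0.051), without mimic replicates 3, 4 and 6 together (0.0862) and in the weighted voom fit (0.066). The list median was 1.70, 1.68, 1.72 and 1.68 in these 4 fits. Oasl2, an oligoadenylate synthetase-like protein, rose by 1.64 ± 0.059 (SE) on the log2 scale, Oas1g by 1.88 ± 0.069, and Irgm1, an interferon-inducible GTPase, by 1.49 ± 0.056 (limma adjusted p of at most 7.45e-12 for these genes). Transcripts of Ifnb1, which encodes interferon-beta, were too few to test, with 2 reads over the control libraries and 15 over the mimic libraries. Ifi27, named as an interferon-inducible gene but not on the list, moved the other way. It fell by 1.04 ± 0.059 (SE) on the log2 scale (limma adjusted p = 7.44e-10) and was below every control in 6 of 6 mimic libraries.

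**Figure D1:**
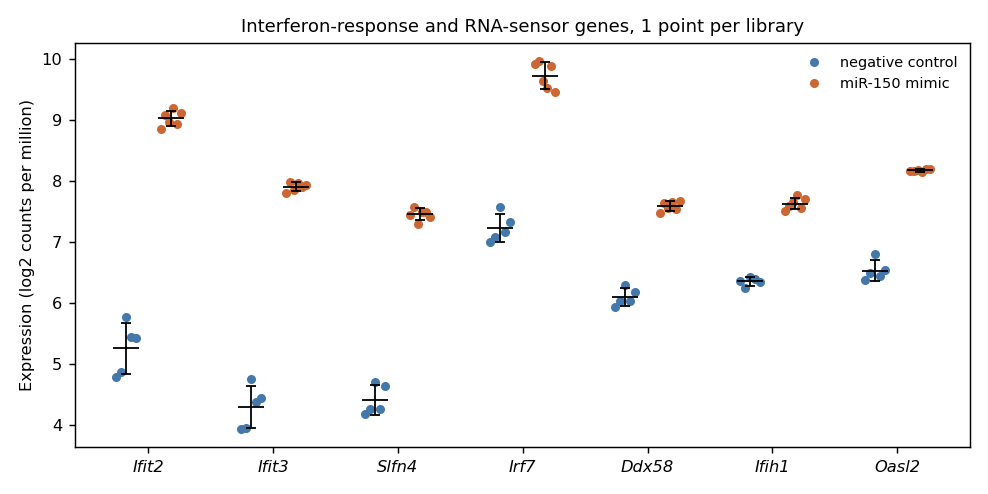
Expression in log2 CPM (y axis) of 7 interferon-response and RNA-sensor genes (x axis), with a point for each library and bars giving the mean and SD of each group. For Ifit3 the 6 mimic libraries average 7.90 and the 5 controls 4.29, with no overlap.

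Receptors and transducers for foreign nucleic acids rose as well: 12 of 21 measured members were higher and 0 lower (median log2 fold change 0.23; camera adjusted p = 2.24e-06, and adjusted p = 0.027 with an estimated correlation). Adjusted over the list alone, 12 were higher and 1 lower. The cytosolic RNA sensors Ifih1 and Ddx58 rose by 1.28 ± 0.049 and 1.49 ± 0.060 (SE) on the log2 scale. Irf7, a transcription factor that amplifies type I interferon production, rose by 2.51 ± 0.12, and Eif2ak2, the kinase activated by double-stranded RNA, by 1.17 ± 0.076 (limma adjusted p of at most 7.18e-09 for these 4). Without the 4 genes that also stand on the interferon list, 8 of 17 members were higher, with a median of 0.051 (camera adjusted p = 0.00611 over the 3 lists that share members with it). Without mimic replicates 3, 4 and 6 the whole list had 13 members higher and a median of 0.15 (camera adjusted p = 9.87e-11, but adjusted p = 0.0862 with an estimated correlation). With an estimated correlation it also missed the threshold without mimic replicate 1 (0.0732), without mimic replicate 2 (0.051) and in the weighted voom fit (0.066). With each library left out in turn its median lay between 0.218 and 0.259.

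Of 25 measured inflammatory activation genes, 12 rose and 1 fell (17 and 2 adjusted over the list alone), with a median log2 fold change of 0.28 and a camera adjusted p of 0.00131. With an estimated correlation the list was no longer past the threshold (adjusted p = 0.567). The chemokine Ccl5 rose by 2.40 ± 0.21 (SE) on the log2 scale from a low level, Ccl2, which recruits monocytes, by 0.87 ± 0.11, and the costimulatory molecule Cd86 by 0.53 ± 0.076, while Socs3, an inhibitor of cytokine signalling, fell by 0.52 ± 0.063 (limma adjusted p of at most 8.92e-05). Complement genes did not pass as a group, with 5 of 17 higher and 3 lower (camera adjusted p = 0.174, or 0.817 with an estimated correlation; 6 and 3 adjusted over the list alone). Without mimic replicates 3, 4 and 6 they passed with the preset correlation only (median 0.37, adjusted p = 0.000566, or 0.442 with an estimated correlation). Cfb, complement factor B of the alternative pathway, rose by 2.21 ± 0.18 and the receptor gene C3ar1 by 0.44 ± 0.042 (limma adjusted p of at most 7.67e-07). Alternative-activation genes showed no common direction, with 2 of 20 higher and 4 lower by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.963). The median of that list was 0.064 (0.0294 to 0.0672 with each library left out in turn, 0.018 without mimic replicates 3, 4 and 6) and its mean -0.051, and 4 members were higher without mimic replicate 1. Among them, the scavenger receptor gene Msr1 rose by 0.55 ± 0.052 and fibronectin, Fn1, fell by 0.75 ± 0.060 (limma adjusted p of at most 7.31e-07).

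Unfolded-protein-response genes went both ways, 9 of 22 higher and 3 lower, with a median log2 fold change of 0.12 (camera adjusted p = 0.00793; 12 and 3 adjusted over the list alone). The list did not pass with an estimated correlation (adjusted p = 0.502). The members with the smallest p were Ddit3 (0.66 ± 0.053, SE), Atf4 (0.34 ± 0.040), the chaperone gene Hspa5 (0.32 ± 0.042) and Asns (0.58 ± 0.090), all higher (limma adjusted p of at most 0.000201). Ddit3, Atf4 and Asns are also known as genes of the amino acid response.

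Antioxidant genes controlled by NRF2 were lower, 14 of 20 by either adjustment, over all genes or adjusted over the list alone, and 0 were higher (median log2 fold change -0.29; camera adjusted p = 4.56e-06, but adjusted p = 0.502 with an estimated correlation). Txnrd1, thioredoxin reductase, fell by 0.34 ± 0.041 (SE), Srxn1, sulfiredoxin, by 0.32 ± 0.040, Gclm, of glutathione synthesis, by 0.31 ± 0.050 and Gsr, glutathione reductase, by 0.20 ± 0.034 (limma adjusted p of at most 0.000538). Without mimic replicates 3, 4 and 6 the list had 12 members lower and 1 higher, with a median of -0.18 (camera adjusted p = 4.23e-07, but adjusted p = 0.373 with an estimated correlation).

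**Figure D2:**
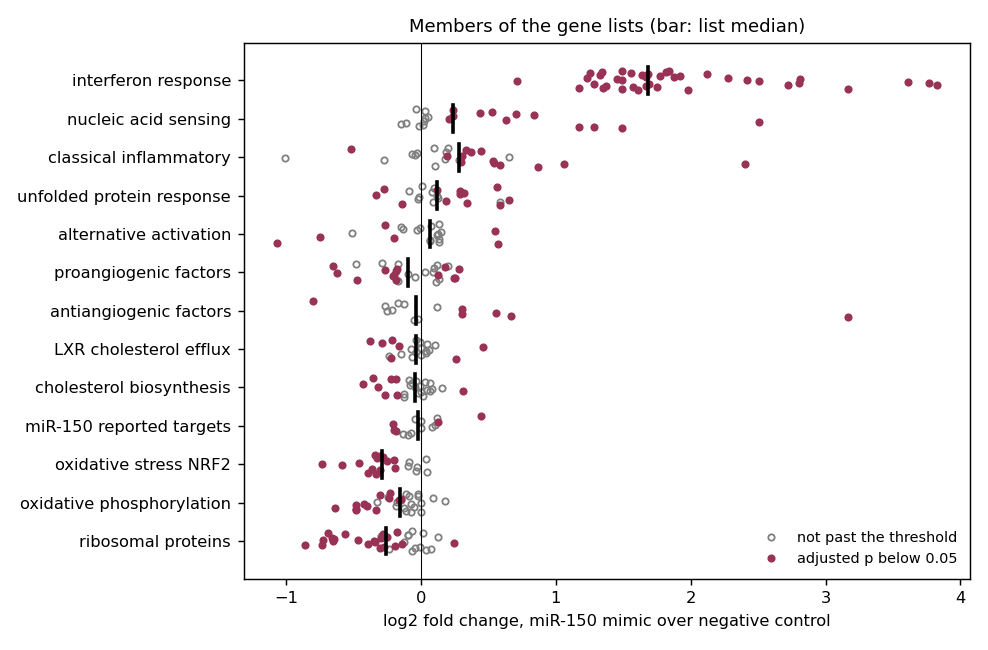
Log2 fold change of mimic over control (x axis) for each measured member of 13 gene lists (y axis). Filled points are genes with a limma adjusted p below 0.05, open points the others, and the bar is the list median, which is 1.68 for the interferon response and -0.29 for NRF2 targets.

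Scd2, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, was lower with the mimic. Its log2 CPM was 4.96 ± 0.055 (SD, n = 5) in controls and 4.59 ± 0.056 (SD, n = 6) with the mimic. The gene (ENSMUSG00000025203) lies on chromosome 19, 44293674 to 44306864 (GRCm38). The fall of 0.38 ± 0.046 (SE) on the log2 scale, 1.30-fold, had a limma adjusted p of 1.47e-05, and all 6 mimic libraries lay below all 5 controls. A two-sided exact permutation test gave p = 0.00216, the smallest that the 462 splits of the libraries allow. The 3664 nt 3′ UTR of Scd2 holds a single site for miR-150-5p, of the 7mer-A1 class, at 544 to 550. The authors' deposited table gives -0.38 for Scd2, with limits of -0.49 and -0.27.

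Abca1, the cholesterol exporter, was higher by 0.26 ± 0.043 (SE) on the log2 scale (limma adjusted p = 0.00037). The list of liver X receptor targets and cholesterol efflux genes, which includes Scd2 and Abca1, had 2 of 21 members higher and 5 lower (camera adjusted p = 0.298), and Npc2, a lysosomal cholesterol carrier, rose by 0.46 ± 0.070 (limma adjusted p = 0.000188). Cholesterol synthesis had 1 of 25 higher and 7 lower (camera adjusted p = 0.211), with Mvd at -0.43 and Ggps1 at 0.31. Its 7 lower genes became 2 to 4 without any of control replicates 1, 2, 4 and 6 or mimic replicates 3, 4 and 6. Fatty acid synthesis and desaturation had 2 of 21 higher and 6 lower (0.298; 3 and 6 adjusted over the list alone), with the desaturase gene Fads1 at -0.21. Fatty acid oxidation had 1 of 22 higher and 5 lower (0.193), with Ppard at -0.31 and Acads at -0.43. That higher count became 0 when, for example, control replicate 1, 3 or 4 or mimic replicate 3 was left out. The counts for cholesterol efflux, cholesterol synthesis and fatty acid oxidation did not change when adjusted over the list alone.

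Genes for angiogenic factors moved in both directions. Among 27 proangiogenic factors 5 were higher and 9 lower (camera adjusted p = 0.711; 9 and 10 adjusted over the list alone), and among 14 antiangiogenic factors 5 were higher and 1 lower (0.594; 5 and 2 adjusted over the list alone). Without control replicate 4 only 3 proangiogenic factors were higher, and without mimic replicate 1 there were 3 antiangiogenic factors lower. For the antiangiogenic list the median log2 fold change was -0.038, the mean 0.23 and the direction of the test upward. That median ran from -0.127 without control replicate 6 to 0.009 without control replicate 3. Leaving out the 1 member that is also on the interferon-response list, 4 of 13 were higher and 1 lower, with a median of -0.054. Hif1a and Igf1 rose by 0.25 ± 0.049 and 0.25 ± 0.054 (SE) on the log2 scale, Kdr, the gene of a receptor for vascular endothelial growth factor, by 0.55 ± 0.050, and the matrix protein gene Thbs1 by 0.31 ± 0.053 (limma adjusted p of at most 0.00373). Kdr and Thbs1 were counted among the higher antiangiogenic factors, although Kdr encodes a growth factor receptor. Vegfa itself measured 0.12 ± 0.052 and did not pass (limma adjusted p = 0.0865), though it passed without mimic replicate 1 (0.15, adjusted p = 0.0205) or control replicate 6 (0.16, adjusted p = 0.0474), and in the weighted voom fit on all libraries (0.15, adjusted p = 0.0135).

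Reported targets of miR-150 did not fall together. Of 14 measured, 3 were lower (Egr2, Gab1 and Cxcr4) and 2 higher (Zeb1 and Mmp14), the same counts as when adjusted over the list alone (median log2 fold change -0.022, and -0.0444 to -0.00665 with each library left out in turn; camera adjusted p = 0.763). Gab1 and Mmp14 were named after their values were seen. These counts were 4 lower and 4 higher without mimic replicate 1, and 5 lower and 2 higher after a correction for transcript length. Only 1 was higher without any of control replicates 1, 2 and 4 or mimic replicates 2 and 3. The chemokine receptor gene Cxcr4 measured -0.19 ± 0.056 (SE; limma adjusted p = 0.0195) and has a 7mer-m8 site at 125 to 131 of its 644 nt 3′ UTR. That call was lost without control replicate 1 (-0.16, adjusted p = 0.0609), without control replicate 2 (-0.18, adjusted p = 0.0537) and without mimic replicates 3, 4 and 6 together (-0.096, adjusted p = 0.189). Zeb1, which carries a 7mer-A1 site, rose by 0.44 ± 0.091 (limma adjusted p = 0.00236). Vegfa is also a reported target, with a 7mer-m8 site at 471 to 477. It measured 0.12 (limma adjusted p = 0.0865) and passed, as higher, only in the alternatives given above. Myb, a well-known target in lymphocytes, was too low to test here, with 10 reads over the controls and 11 over the mimic libraries.

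**Figure D3:**
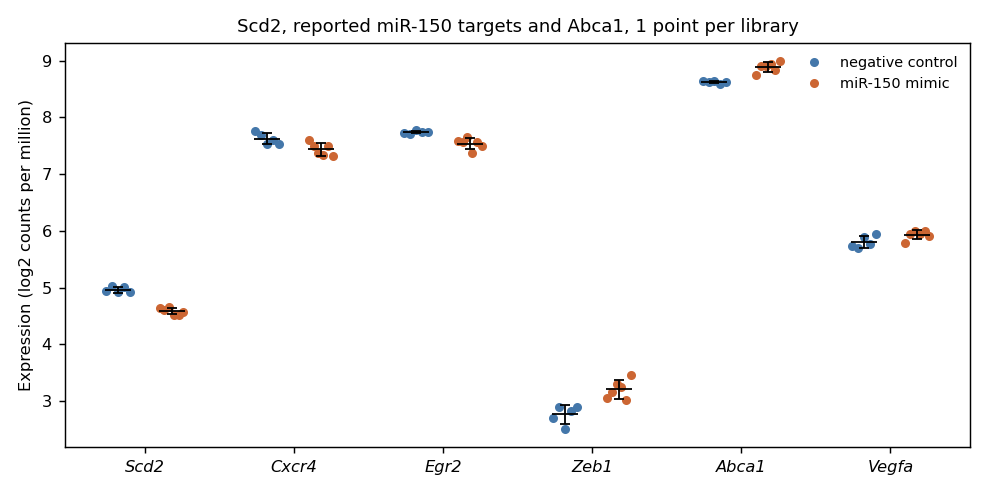
Expression in log2 CPM (y axis) of Scd2, the reported miR-150 targets Cxcr4, Egr2, Zeb1 and Vegfa, and Abca1 (x axis). There is a point for each library, and bars give the mean and SD of each group. Scd2 averages 4.59 with the mimic and 4.96 in controls without overlap.

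Before any adjustment for length, genes with a miR-150-5p site in the 3′ UTR were not lower as a class than genes without one. The 3064 genes with a site had a median log2 fold change of 0.020 and the 8590 without a site -0.0076, and the camera test did not pass, with its direction upward. A two-sided exact permutation test of the difference in medians over the 462 splits of the libraries, added after the camera result was seen, gave p = 0.136. A share of 12.8% of the first and 16% of the second were called lower. Genes with a site had longer 3′ UTRs, with a median of 2261 nt against 884 nt without a site. Fold change rose with transcript length, so these comparisons cannot separate an effect of the site from that trend. After a per-library correction for transcript length the median of the genes with a site was -0.0091, and the camera test again did not pass. Without that correction, random sets matched on 3′ UTR length and expression had a median of 0.035. Of these 1000 sets, 0 were as low as the genes with a site. They were drawn from all genes, those with a site included, and take no account of genes that vary together. Among 200 control 7-mers of the same GC count, 82 gave a median as low. These controls were not matched on length or expression, and each was a single 7-mer, whereas the site set joined several classes of site. The 580 genes with the strongest class of site, the 8mer, had a median of 0.036 against 0.041 in their matched sets, of which 263 of 1000 were as low. For the 1944 genes with a 7mer-m8 or 8mer site the values were 0.028 and 0.040, with 8 of 1000 as low. For the 2916 genes with a site in the coding sequence they were 0.029 and 0.0045, with 1000 of 1000 as low, although those sets were matched on 3′ UTR length and not on coding length.

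**Figure D4:**
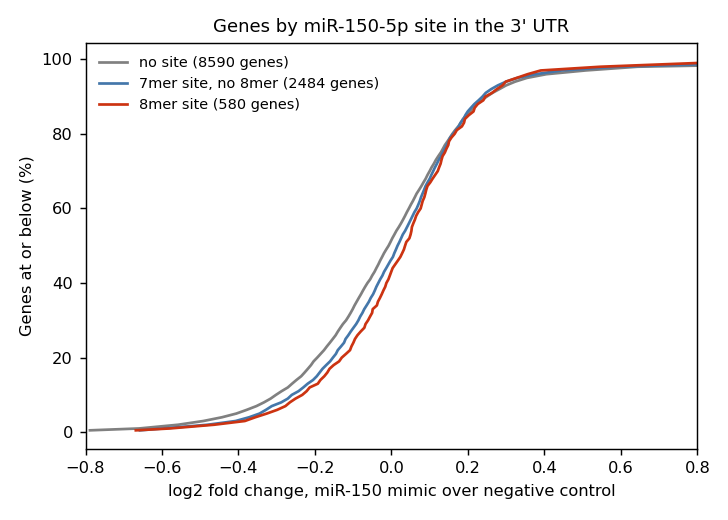
Share of genes (y axis, %) at or below each log2 fold change of mimic over control (x axis), for genes with no miR-150-5p site in the 3′ UTR, a 7mer site or an 8mer site. The 3 curves lie close together; the median of the 8mer genes is 0.036.

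Short and structural RNAs made up most of the largest falls. They were the histone H4 genes Hist1h4h (log2 fold change -1.79), Hist1h4c (-1.17), Hist4h4 (-1.17) and Hist1h4f (-1.15), and the small RNAs Rmrp (-1.47), Rn7sk (-1.42), Scarna6 (-1.27), Snord17 (-1.10) and Rn7s6 (-1.05), with limma adjusted p between 0.00985 and 0.0369. Each of these 9 was below every control in 5 of 6 mimic libraries, and all 9 belong to multicopy families or are structural RNAs with related copies, so their single values are uncertain. Of 43 histone genes, a group assembled after the values were seen, 32 were lower and 1 higher, with a median of -0.87. Without mimic replicates 3, 4 and 6 none of the 9 passed (limma adjusted p from 0.136 to 0.368). Their log2 fold changes then ran from -0.51 for Hist1h4f to -1.14 for Hist1h4h. In the same fit 7 histone genes were lower, with a median of -0.43. Without a filter on low values Hist1h4c, Hist1h4f, Rn7sk, Scarna6, Snord17 and Rn7s6 did not pass either (limma adjusted p from 0.0512 to 0.109), at the same log2 fold changes as reported. The calls of Hist1h4f, Rn7sk, Scarna6 and Snord17 were lost when single libraries were left out. They were lost for Hist1h4f without any of mimic replicates 3, 4 and 6 or control replicates 1, 2, 3 and 6 (log2 fold change from -0.979 to -1.18), and for Rn7sk without any of mimic replicates 3, 4 and 6 or control replicates 2 and 3 (-1.29 to -1.37). Scarna6 lost its call without any of mimic replicates 2, 3, 4 and 6 or control replicates 1, 2, 3 and 6 (-1.07 to -1.33), and Snord17 without any of mimic replicates 2, 3, 4 and 6 or control replicates 2 and 3 (-0.939 to -1.08).

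Ribosomal protein mRNAs were lower in 20 of 34 cases and higher in 1 (23 and 1 adjusted over the list alone), with a median log2 fold change of -0.26 (camera adjusted p = 3.67e-06, but adjusted p = 0.567 with an estimated correlation). Rps7 fell by 0.69 ± 0.13 (SE), Rps19 by 0.66 ± 0.13, Rpl35 by 0.74 ± 0.15 and Rpl8 by 0.34 ± 0.077 on the log2 scale (limma adjusted p of at most 0.00474). Nuclear-encoded genes of oxidative phosphorylation were lower in 12 of 30 cases and higher in 0 (17 lower and 1 higher adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.000224, but adjusted p = 0.734 with an estimated correlation). Without mimic replicate 1 there were 19 lower and 2 higher, and without mimic replicate 4 or 6 there were 7 lower and 0 higher. Ndufa1 fell by 0.40 ± 0.085, Cox5a by 0.48 ± 0.11, Cox4i1 by 0.33 ± 0.083 and Ndufa2 by 0.48 ± 0.12 (limma adjusted p of at most 0.0107). In mimic replicates 3, 4 and 6 genes under 1000 nt lay lowest among the 11 libraries, with mean deviations of -0.148, -0.194 and -0.16. Without these 3 libraries 5 ribosomal protein genes were lower and their list passed with the preset correlation only (median -0.14, camera adjusted p = 4.62e-05, but adjusted p = 0.537 with an estimated correlation). The oxidative phosphorylation list then did not pass with either (median -0.049, adjusted p = 0.0887 and 0.823), with 0 members lower by limma (4 at an unadjusted p under 0.05), and Rps7, Rps19, Rpl35, Ndufa1, Cox5a, Cox4i1 and Ndufa2 lost their calls, at log2 fold changes of -0.46, -0.52, -0.54, -0.26, -0.28, -0.16 and -0.26 in that order. Without a filter on low values Cox4i1 and Ndufa2 did not pass (limma adjusted p = 0.0751 and 0.0628), at the same log2 fold changes as reported. Mitochondrially encoded genes showed 0 of 7 members past the threshold with limma, by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.979). At an unadjusted p under 0.05 there was 1, and the weighted voom fit called 1. The members with the smallest p were mt-Nd1 (-0.15) and mt-Nd6 (0.21), and mt-Nd6 passed without mimic replicate 1 (0.28) and in the voom fit (0.31). The median of that list was 0.026 and its mean 0.016, with the direction of the test downward. Its median ran from -0.0409 without mimic replicate 3 to 0.0807 without mimic replicate 2, and was 0.13 after a correction for transcript length. Without mimic replicates 3, 4 and 6 together it was -0.16, with 1 member called lower by limma and 0 higher.

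Fold change also varied with transcript length. Genes whose longest transcript was at most 500 nt had a median log2 fold change of -0.21, and those longer than 5000 nt 0.071. Across 11744 protein-coding genes, which are not independent replicates, Spearman's rho between fold change and length was 0.283. After a per-library correction for length the medians were -0.11 for ribosomal protein genes and -0.096 for oxidative phosphorylation genes, with both lists past the threshold by the preset correlation (camera adjusted p = 0.00115 and 0.0419) and not with an estimated correlation (adjusted p = 0.278 and 0.703). After the correction 25 histone genes were lower, with a median of -0.71. Mimic replicate 1 did not share the shift. Rn7sk took 0.483% of its reads, against 0.111 to 0.192% in the other mimic libraries and 0.347 to 0.661% in controls. For genes under 1000 nt its mean deviation was 0.153, above every control (0.053 to 0.119). The other mimic libraries were not shifted alike, with mimic replicate 5 at -0.0137 and mimic replicates 2, 3, 4 and 6 between -0.0957 and -0.194. The interferon-response genes, in contrast, stood at 0.958 to 1.03 of the way from the control mean to the mean of the other mimic libraries in each of the 6 mimic libraries.

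**Figure D5:**
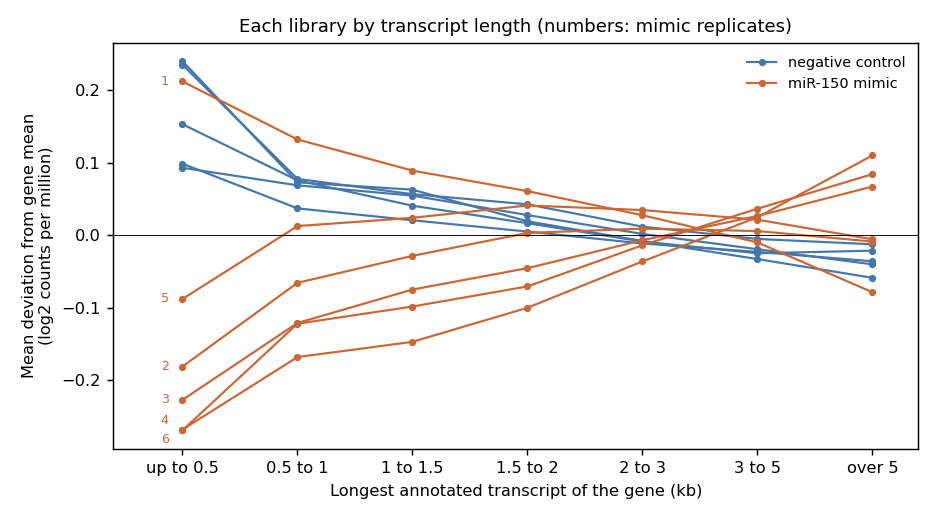
Mean deviation of each library from the gene mean in log2 CPM (y axis) by the length of the longest annotated transcript in kb (x axis), with a line for each of the 5 control and 6 mimic libraries. In the shortest class mimic replicate 1 stands at 0.21, among the controls, and the other mimic libraries between -0.088 and -0.27.

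Macrophage identity genes did not move as a set, with 4 of 19 higher and 7 lower (camera adjusted p = 0.898; 4 and 8 adjusted over the list alone; median 0.0047, mean 0.048, direction of the test downward). Their median ran from -0.0381 without mimic replicate 1 to 0.0477 without mimic replicate 4. Fcgr1, the high-affinity IgG receptor, rose by 1.32 ± 0.078 (SE) and the chemokine receptor gene Ccr2 by 0.81 ± 0.098 on the log2 scale (limma adjusted p of at most 1.5e-05). Genes typical of resident peritoneal macrophages had 2 of 13 higher and 1 lower (camera adjusted p = 0.804; 1 and 1 adjusted over the list alone), with Cd5l at 0.26 and Saa3 at -0.49 (limma adjusted p = 9.8e-05 and 0.00832). The call of Saa3 was lost without mimic replicates 3, 4 and 6 (-0.29).

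No list of markers of another cell type passed as reported. With the same counts over all genes and adjusted over the list alone, 0 of 9 fibroblast markers were called by limma (1 at an unadjusted p under 0.05, 2 called by the weighted voom fit). Of 10 mesothelial markers 1 was lower, of 5 B cell markers 2 were lower, of 12 dendritic cell markers 1 was higher and 2 lower, and of 6 neutrophil and 4 endothelial markers 1 was higher and 1 lower in each. The camera adjusted p was 0.16 for fibroblasts, 0.222 for mesothelial cells, 0.222 for B cells, 0.763 for dendritic cells, 0.763 for neutrophils and 0.985 for endothelium. Single markers chosen by the naming rule were Col6a2 (log2 fold change -0.48) and Col1a1 (-0.36) for fibroblasts, Krt8 (-0.51) and Aldh1a2 (-0.19) for mesothelial cells, and Ighm (-0.75) and Cd22 (-0.17) for B cells. They were Bst2 (1.61), which is also on the interferon-response list, and Batf3 (-0.53) for dendritic cells, Padi4 (0.38) and S100a8 (-0.56) for neutrophils, and Kdr (0.55) and Vwf (-0.63) for endothelium. Of these 12, Col6a2, Col1a1 and Aldh1a2 did not pass. Col6a2 passed without any of control replicate 2 and mimic replicates 1, 2 and 5 (-0.494 to -0.608), without a filter (-0.48), after the length correction (-0.52) and in the voom fit (-0.61). Col1a1 passed in the voom fit (-0.47), and Aldh1a2 in the voom fit (-0.22) and without mimic replicate 2 (-0.25). Ighm lost its call without any of control replicates 1, 2 and 3 or mimic replicates 3 and 6 (-0.584 to -0.703), and Krt8 without control replicate 1 (-0.46). Without mimic replicates 3, 4 and 6 together Ighm, Krt8 and S100a8 all lost their calls (-0.45, -0.25 and -0.36).

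The fibroblast list passed, as lower, without mimic replicate 2 (median -0.40, adjusted p = 0.025) and in the weighted voom fit (-0.39, adjusted p = 0.0472), in each case with the preset correlation only. With an estimated correlation (0.725 for this list) the adjusted p was 0.818 as reported, 0.642 without mimic replicate 2 and 0.715 in the voom fit. The fibroblast median was 0.012 without mimic replicates 3, 4 and 6. Counts in the fibroblast, mesothelial, B cell, dendritic cell and resident macrophage lists moved by 1 member when some single libraries were left out. For the 4 endothelial markers the median was 0.051 (0.00364 to 0.103 with each library left out in turn, 0.25 without mimic replicates 3, 4 and 6) and the mean 0.0062, with the direction of the test downward. Lists for T and NK cells, eosinophils, mast cells and erythroid cells had 1, 2, 1 and 0 members high enough to test.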

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

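The test of the place of mimic replicate 1 on the interferon genes and the relation to length among protein-coding genes were chosen after those results had been seen, and the estimated correlation was brought to bear on the ribosomal protein percentile after that value was known. A library stood apart from the others of its group in 19 of 270 groups of values examined, where 5% would be about 13.5. The groups share libraries, genes and lists and are not independent, so this comparison is not a test of chance. Each case below gives the gap to the nearest library as a share of the group's whole range.

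Mimic replicate 1 accounted for 6 of the 19. It was the highest mimic library for the share of reads from Rn7sk (gap share 0.782), for Rmrp (0.79), Snord17 (0.654), Ndufa1 (0.636), Saa3 (0.64) and Rps19 (0.742). Its log2 CPM for Rmrp was 9.42, against 7.67 to 8.04 in the other mimic libraries. Among the other mimic libraries, replicate 2 was lowest for the share of mitochondrially encoded reads (0.639; 0.253%), replicate 4 for the alternative-activation mean (0.69) and replicate 6 for Btg2 (0.807).

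Control replicate 3 was the highest control for the inflammatory activation mean (0.789), Ms4a4c (0.873), Mcm6 (0.73), Fcgr1 (0.98) and Hspa5 (0.839). Its log2 CPM for Fcgr1 was 7.11, against 6.68 to 6.69 in the other controls, and below the mimic mean of 8.09. Control replicate 6 was lowest for the B cell marker mean (0.869), control replicate 2 highest for fatty acid oxidation (0.793) and lowest for Dcp2 (0.74), control replicate 4 lowest for glycolysis (0.729) and control replicate 1 lowest for immediate early genes (0.838).

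Mimic replicate 1 lay near the controls for most called genes, at 0.342 of the way from the control mean to the other mimic libraries for the higher genes outside the interferon list and 0.214 for the lower genes. An untreated or wrongly labelled library is argued against by its interferon genes, which lay 0.98 of the way. The length trend alone is argued against too, since after a correction for transcript length the lower genes of this library still lay only 0.342 of the way. What sets this library apart, such as a weaker response outside the interferon genes or a difference in RNA handling, stays open, because the labels give no batch.

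Short transcripts were lower with the mimic, and a difference in how libraries kept short RNA may account for part of it. After the length correction 1931 genes were lower, 1573 of them among the 1895 lower as reported. That argues against the trend as the whole cause of the lower genes. The count takes in genes of every length, so it does not test the short transcripts by themselves. A difference between RNA classes alone is argued against by the Spearman rho of 0.283 among protein-coding genes. Ribosomal protein genes lay at the 0.5 percentile of 1000 random sets matched on length and expression, under the bound of 2.5 set beforehand, and oxidative phosphorylation at the 12.4 percentile, but random sets do not vary together as ribosomal protein genes do (estimated correlation 0.396; adjusted p = 0.567). Whether those genes fell beyond other short mRNAs therefore stays open, as does a technical source for the trend, since fragmentation and size selection were not measured per library.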

How the results depend on the processing

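The omission of mimic replicates 3, 4 and 6, the correction for transcript length, the filter on mean expression and the runs that join an estimated correlation to another choice were chosen after seeing the data. No gene or list past the threshold as reported changed direction under the alternatives run. Medians of lists not past the threshold changed sign in 35 of 650 comparisons; without mimic replicates 3, 4 and 6, for example, fibroblast markers went from -0.30 to 0.012 and mesothelial markers from -0.20 to 0.084. Scd2 stayed lower and past the threshold under each except a required log2 fold change of at least 1 (-0.38), which also left 149 genes higher and 44 lower. An adjusted p below 0.01 left 967 and 792, fewer by construction. Without mimic replicates 3, 4 and 6, with fewer samples, 1200 genes were higher and 886 lower. With each library left out in turn, 1490 to 2694 genes were higher and 1405 to 2500 lower, both highest without mimic replicate 1. With library totals as the only scaling, 42.9% of calls were higher (1598 higher, 2126 lower) against 51.3% as reported. The weighted voom fit called 2960 and 2665.

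The number of lists past the threshold was 7 as reported, 2 with an estimated correlation, 11 with fry, which asks a different question, and 11 without a filter. With camera and an estimated correlation it was 2 after the length correction and with each of 9 libraries left out, always the interferon-response and nucleic acid lists. It was 0 in 4 runs, with 3 lists at an unadjusted p under 0.05 without mimic replicate 1, 2 without mimic replicate 2, 4 without mimic replicates 3, 4 and 6, and 2 in the weighted voom fit. Control 7-mers as low as the miR-150-5p site numbered 49 without a filter and 129 after the length correction; the cause was not tested. Median fold changes of site-bearing genes lay between -0.0091 and 0.036, on either side of 0, none past the threshold. For named genes other than Scd2, 2175 comparisons across alternatives kept their side of the threshold, 138 lost it and 15 gained it. For lists the numbers were 813, 7 and 12. This list tally leaves out the runs that join an estimated correlation to another choice, in which more lists lost the threshold.

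Replicate numbers did not pair the samples: correlations of deviations between same-numbered libraries ran from -0.061 to 0.062, and only replicate 4 correlated best with its own number. With the replicate block 1777 genes were higher and 1796 lower. The planned negative binomial fits were not run, although whole reads were recovered. Depth limits low genes such as Ifnb1 and Myb, with at most 15 reads over a group.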

Other observations

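The tests of other cell types, of Ifnb1 and of the rank of the site among all 7-mers were chosen after those results had been seen.

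Stress and growth-control genes outside the report's groups also moved singly. Of 23 p53 and apoptosis genes 8 were higher and 3 lower (camera adjusted p = 0.193; 10 and 3 adjusted over the list alone), with the cell-cycle inhibitor Cdkn1a at a log2 fold change of 0.47 ± 0.063 (SE) and Casp8 at 0.31 ± 0.042. Without mimic replicate 1, 5 were lower. Cell cycle genes had 1 of 32 higher and 1 lower by either adjustment, over all genes or adjusted over the list alone (0.732), namely Mcm6 at 0.25 and Cenpa at -0.56, and 4 were higher and 2 lower without mimic replicate 1. Immediate early genes had 4 of 20 higher and 6 lower by either adjustment (0.49), with Klf6 at 0.33 and Btg2 at -0.24; 2 were higher without any of control replicates 4 and 6 or mimic replicates 3 and 6. The decapping enzyme gene Dcp2 (0.54 ± 0.068) and the exonuclease gene Xrn1 (0.44 ± 0.081) were higher on a list of small RNA machinery with 5 of 21 higher and 2 lower (0.211; 7 and 3 adjusted over the list alone). On that list 9 were higher and 1 lower without mimic replicate 1, and 3 were higher without any of control replicates 1, 2 and 4 or mimic replicates 3, 4 and 6, while 0 were lower without any of control replicates 2, 3 and 4. Its median fell from 0.085 to 0.0032 after the length correction and to -0.0028 without mimic replicates 3, 4 and 6 together.

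Genes for taking up and digesting material went both ways, with 6 of 26 higher and 6 lower (camera adjusted p = 0.763; 6 and 7 adjusted over the list alone). The receptor genes Axl and Cd300lf, which take part in the handling of apoptotic cells, rose by 0.90 ± 0.069 and 0.74 ± 0.053 (SE) on the log2 scale (limma adjusted p of at most 5.05e-08). Glycolysis had 1 of 19 higher, Hk2 at 0.20, and 8 lower, such as Gpi1 at -0.23 (0.138; 2 and 9 adjusted over the list alone), but only 2 to 5 lower with any library other than mimic replicates 1 and 5 left out. Hypoxia genes had 3 of 19 higher and 5 lower (0.298; 3 and 6 adjusted over the list alone), with P4ha1 at 0.45 and Ndrg1 at -0.36, and 3 lower without any of control replicates 1, 2 and 3 or mimic replicates 2 and 4.

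The rise of interferon-response genes is a candidate response to the mimic RNA itself. The sample titles call the comparison group only a negative control, and do not say whether it received an unrelated mimic. No sample titled as untransfected was analysed here. The length trend is argued against, since the list median was 1.74 after the length correction, and no single library decided it, since the lowest median with a library left out was 1.64. Cells of another type were tested by 6 marker lists, whose highest median was 0.051, for 4 endothelial genes that went both ways (0.00364 to 0.103 with each library left out in turn, 0.25 without mimic replicates 3, 4 and 6), under the bound of 0.5 in each case; types with fewer than 3 measured markers stay untested. An earlier form of that test, tried first and replaced, set the summed CPM of lymphocyte markers with the mimic (1260) against that of the interferon list (7240) and did not decide, because Il7r and Cd22 were abundant in both groups (939 and 175 CPM in controls, 1100 and 156 with the mimic). Sensing of the mimic and repression through its seed cannot be told apart: Ifnb1 averaged 0.102 CPM with the mimic, and a two-sided exact permutation test over the 462 splits gave p = 0.0563.

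The hypothesis that the mimic lowered site-bearing mRNAs as a class was examined against matched sets, control 7-mers and all 7-mers. The difference at issue is that from sets matched on 3′ UTR length and expression, of which 0 of 1000 were as low (8 for 7mer-m8 or 8mer sites and 263 for 8mer sites), so those sets cannot test whether length or expression accounts for it. Of 200 control 7-mers 82 were as low, but they were not matched on 3′ UTR length or expression. They therefore cannot decide whether base composition accounts for the difference. After regression on length, expression and GC content, the site TTGGGAG ranked 4115 from the lowest of 16108 7-mers, outside the lowest 5%. Repression of single genes such as Scd2 stays open.

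Other splits of the 11 libraries into 5 and 6 were drawn, 100 of the 462 possible with the real split included. For the 3892 changed genes, 2 of 100 splits gave as many, under the bound of 5% set beforehand. That result covers only the assignment of these libraries to groups, and not the spread between animals or cultures, since the replicates may be technical. The split other than the real one, with 4934 genes, grouped mimic replicate 1 with the controls, which points to a structure of the samples. For the interferon-response list this permutation of the groups left the real split as the strongest, 1 of 100, with a camera p of 4.23e-63 against 1.16e-42 for the next. For the 7 lists past the threshold 38 of 100 splits gave as many, up to 14. In the same permutation 60 of 100 splits gave the site-bearing genes a camera p as small as the real 0.301, the smallest being 0.00449. Chance is not excluded for the number of lists or for the site-bearing genes.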
